A study of Homo sapiens with 12 samples.

How the data were processed

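The series holds 12 RNA-seq libraries of 2 human colon cancer cell lines, HCT116 and RKO, kept for 48 h in cystine-free medium or in medium with 25 µM cystine, in 4 groups of 3. Total RNA was extracted with Trizol, per the labels' protocols. The deposited table gives an estimated count and an FPKM value (fragments per kilobase and library size) for 33958 genes in each library. The estimated counts and the FPKM values were computed by the authors, and the submitters' processing notes name Bowtie 0.12.2, HISAT2 2.0 and StringTie 1.3.0 without a role for each. The same notes name the mouse builds mm8 and GRCm38, while the samples and gene identifiers are human: 33810 of the identifiers were found in GENCODE 29, and 99.99% of these overlapped its genes on GRCh38, so coordinates are given for that build as the table holds them. The counter, the annotation release and any filter are not stated.

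The deposited estimated counts were whole numbers and were used without rounding. They piled up at multiples of 4, and their variance was 3.66 to 3.75 times the mean for genes with a mean of 1 to 3 counts. About 4 counts were therefore taken to stand for 1 fragment, an inference that could not be checked. A floor of 12 counts (3 fragments) per library was used. Totals were 50.6 M to 66.7 M counts per library. For the 3740 genes with over 2000 counts in every library, count and FPKM kept a fixed ratio up to a factor per library.

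Genes with an FPKM of at least 1 in at least 3 libraries were tested, 13504 in all. The plan named edgeR for raw counts and limma on log2(FPKM + 1) for FPKM values. The table held estimated counts and FPKM values. The choice of edgeR was made once the table was seen, since the estimated counts were whole numbers. Counts were scaled with TMM and fitted in edgeR 4.0.16 (quasi-likelihood F test, 1 mean per group, R 4.3.3), and p-values were adjusted by Benjamini and Hochberg within each comparison, with calls at an adjusted p under 0.05. The comparisons were the cystine effect in HCT116, the same in RKO, their difference (the interaction) and the mean difference between the lines. Standard errors of the log2 fold changes were back-calculated, as the absolute log2 fold change divided by the square root of the F statistic. They are therefore approximate. Gene lists fixed before any value was seen were tested with camera in limma 3.58.1 with a preset correlation between genes of 0.01, for lists with at least 3 tested members. Camera with an estimated correlation and fry were the alternatives.

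Genes were named by a rule written before any value was seen. It took the 8 largest rises and 8 largest falls in each cystine test (6 and 6 in the other comparisons) among called genes with separated replicates and a group mean of at least 5 FPKM, the 4 members with the smallest p of each called list, the epithelial and mesenchymal members for the line difference, and 20 genes named whatever their result. Clone-style, mitochondrial and histone genes were left out of the largest changes. Other genes in the text, among them NQO1, TKT, EGR1, KLF10, PRDX2, MT2A and those of the other observations, were chosen after their values were seen, as examples of a list. Some genes that the rule names are not reported here. Where 2 entries shared a symbol, the one with the higher mean was used. CBS, one of the 20, was close to 0 in all libraries and was left out by the FPKM filter. Its near-identical copy CBSL makes its counts uncertain, and whether reads went to that copy was not tested.

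The programs were tested on simulated data, 5 simulations per comparison with 200 of 13504 genes changed. For HCT116 the test recovered 13.6% of the genes changed 1.5-fold, 50.4% at 2-fold, 73.6% at 3-fold and 81.2% at 4-fold, with 5.5% of the calls false. For RKO these were 21.2%, 50.0%, 76.0% and 81.6%, with 7.1% false, for the interaction 2.4%, 26.4%, 57.6% and 67.6%, with 7.2% false, and for the line difference 49.2%, 75.6%, 88.0% and 92.0%, with 3.8% false. In these simulations the false share of the cystine tests thus lay above the nominal 5%, in HCT116 by little (32 of 579 calls). The real tests called a larger share of genes than was changed here, so recovery and false shares may not carry over. A first version with 1 simulation per comparison was replaced by the pooled one after its false share in the interaction exceeded the limit set for it.

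The alternatives tried were a pseudocount of 0.1 on log2 FPKM, no filter and a filter at 5 FPKM, median-ratio and quantile scaling, no variance trend, a robust variance, library weights, the replicate number as a block, each library left out in turn, each line fitted alone, stricter thresholds, and each medium alone for the line difference. DESeq2 1.42.0, counts divided by 4, KEGG and GO terms and counts summed over overlapping models were added after seeing the data. The limma test on log2(FPKM + 1), planned for FPKM values, was kept as an alternative to edgeR. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.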

Results

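HCT116 and RKO are established human colon cancer cell lines. Their transcriptomes were profiled by RNA-seq after 48 h in medium without cystine or with 25 µM cystine, the oxidised form of cysteine that cells import through the exchanger built from SLC7A11 and SLC3A2. Each of the 4 groups held 3 libraries, 12 in all. The labels named the cystine-free libraries as controls. Every cystine difference is given as 25 µM cystine relative to cystine-free medium, so a gene that was more abundant without cystine has a negative value. The deposited estimated counts summed to between 50.6 M and 66.7 M per library. If about 4 counts stood for 1 sequenced fragment, as inferred from the values alone, this gives 12.6 M to 16.7 M fragments. Libraries of the same group correlated at r = 0.974 to 0.983 across genes (log2 FPKM), libraries of the same line in the other medium at 0.934 to 0.954, and libraries of the other line at 0.753 to 0.801. Mitochondrially encoded genes took 16.3% ± 0.557 of the counts in cystine-free HCT116 and 15.7% ± 2.36 with cystine, against 8.77% ± 0.252 and 10.6% ± 2.12 in RKO (mean ± SD, n = 3 libraries). The labels do not say whether the replicates came from separate cultures. The p-values measure the spread between these libraries, and whether this covers the spread between independent cultures is unknown. Of 13504 genes tested with edgeR, values are given as mean FPKM ± SD over 3 libraries and as log2 fold changes with their standard errors (SE).

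The first question was which genes responded to cystine in HCT116. With 25 µM cystine, several genes of cystine import, glutathione and haem breakdown were far lower than without it. SLC7A11, the light chain of the cystine importer (chromosome 4, 138164097 to 138242349, GRCh38), had 55.2 ± 9.55 FPKM in cystine-free medium and 9.19 ± 2.10 with cystine (log2 fold change −2.60, SE 0.21, adjusted p = 1.75e-05). Its heavy chain SLC3A2 went from 79.2 ± 9.40 to 27.5 ± 2.83 FPKM (−1.55, SE 0.10). CHAC1, which degrades glutathione (chromosome 15, 40952962 to 40956512), fell from 21.8 ± 9.71 to 2.97 ± 1.14 FPKM (−2.87, SE 0.37, adjusted p = 0.000312). HMOX1, the haem-degrading oxygenase (chromosome 22, 35380361 to 35390293), fell from 163 ± 34.0 to 6.33 ± 0.379 FPKM (−4.70, SE 0.20, adjusted p = 3.81e-07). Cholesterol synthesis genes rose, led by INSIG1, a sterol-regulated retention factor, from 1.21 ± 0.141 to 7.17 ± 0.754 FPKM (2.55, SE 0.18).

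In all, 3937 genes passed the edgeR quasi-likelihood test in HCT116 (Benjamini-Hochberg adjusted p under 0.05), 1979 higher and 1958 lower with cystine, of which 408 and 419 changed at least 2-fold. Of 18 tested targets of the integrated stress response, the programme run by the transcription factors ATF4 and DDIT3 (CHOP), 15 fell and 0 rose (16 fell adjusted over the list alone), with a median log2 fold change of −2.25. Among them were DDIT3 itself (−3.70, SE 0.29), the secreted stress cytokine GDF15 (−3.27, SE 0.17), SESN2 (−2.68, SE 0.14) and PPP1R15A (−2.49, SE 0.10). The ATF4 transcript stood at 218 ± 0.665 FPKM without and 193 ± 12.4 with cystine (adjusted p = 0.158). ASNS, DDIT4 and TRIB3 of the same list fell by 1.76, 2.48 and 2.49 on the log2 scale. Amino acid transporters fell in 10 of 15 members and rose in 0 (10 adjusted over the list alone), among them SLC7A5 (−1.47, SE 0.10) and SLC7A1 (−1.35, SE 0.09). Of the 20 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, 13 fell and 2 rose (13 and 2 adjusted over the list alone; adjusted p = 0.0816 with an estimated correlation). WARS was at −1.92 (SE 0.13) and SARS at −1.40 (SE 0.09). PHGDH of serine synthesis fell by 0.89 on the log2 scale. Its list, serine and one-carbon metabolism, was not called by camera (adjusted p = 0.0684), with 5 members lower and 4 higher of 11. PSAT1 of this list had 285.04, 280.97 and 291.84 FPKM without and 112.07, 111.63 and 81.63 with cystine. MTHFD2 had 178.31, 167.74 and 185.2 FPKM without and 71.44, 78.7 and 69.12 with cystine. CTH, which makes cysteine from cystathionine, had 6.75 ± 0.531 FPKM without and 6.51 ± 0.589 with cystine (adjusted p = 0.76).

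Of 20 targets of the antioxidant regulator NRF2, 14 fell with cystine in HCT116 and 2 rose (15 and 3 adjusted over the list alone). The ferritin chains FTH1 (chromosome 11, 61959718 to 61967634) and FTL, which store iron, fell from 2333 ± 331 to 487 ± 27.4 FPKM (−2.28, SE 0.13) and from 2425 ± 445 to 753 ± 31.4 FPKM (−1.70, SE 0.19). The glutathione synthesis genes GCLC (−1.53, SE 0.10) and GCLM (−1.99, SE 0.15) and the sulfiredoxin gene SRXN1 (−2.03, SE 0.14) fell as well. TXNRD1 fell by 1.94 on the log2 scale (SE 0.36, adjusted p = 0.0027). FTH1 and FTL have processed pseudogenes, so the counts of both are uncertain where reads could be shared. The glutathione and thioredoxin list moved both ways, with 9 members lower and 4 higher (9 and 7 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation). The peroxiredoxin PRDX2 rose by 0.97 (log2). The selenoenzyme GPX4, which reduces lipid peroxides, had 29.1 ± 4.04 FPKM without and 37.7 ± 3.95 with cystine (adjusted p = 0.0614). Ferroptosis regulators and markers, which share FTH1, FTL and SLC7A11 with other lists, fell in 6 of 20 members and rose in 4 (7 and 5 adjusted over the list alone; adjusted p = 0.0527 with an estimated correlation). TFRC, the transferrin receptor, had 62.4 ± 0.549 and 54.4 ± 6.38 FPKM (adjusted p = 0.414). Iron-sulfur assembly and iron handling, with FTH1 and FTL among its members, fell in 4 of 19 and rose in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.091 with an estimated correlation).

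Endoplasmic reticulum chaperones and unfolded protein response genes fell in 11 of 18 members and rose in 0 (11 adjusted over the list alone). HSPA5, the main lumenal chaperone, went from 612 ± 70.3 to 206 ± 2.60 FPKM (−1.58, SE 0.10). Immediate early and AP-1 genes fell in 13 of 18 and rose in 0 (14 adjusted over the list alone). JUN (chromosome 1, 58780788 to 58784327) went from 24.5 ± 2.49 to 3.32 ± 0.356 FPKM (−2.90, SE 0.12) and FOSL1 at −2.12 (SE 0.15). Of the p53 targets 9 of 19 fell and 2 rose (11 and 2 adjusted over the list alone; adjusted p = 0.0877 with an estimated correlation). Among them were GADD45A (−1.69, SE 0.21) and TNFRSF10B (−1.31, SE 0.09). CDKN1A, the p21 cell cycle inhibitor, varied between the cystine-free libraries (56.4 ± 37.3 FPKM, against 27.0 ± 3.09 with cystine, adjusted p = 0.183). The cystine-free libraries had 69.58, 85.34 and 14.35 FPKM, so the third stood apart. Across genes (log2 FPKM) the third correlated with the cystine libraries of HCT116 at r = 0.949 to 0.951, and the others at 0.934 to 0.945. Autophagy and lysosome genes fell in 7 of 22 and rose in 0 (7 adjusted over the list alone; adjusted p = 0.091 with an estimated correlation), led by the adaptor SQSTM1 (−1.83, SE 0.13).

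Higher with cystine in HCT116 were 18 of 20 cholesterol synthesis genes, with none lower (19 adjusted over the list alone; median 1.39). SQLE rose by 1.44 (SE 0.09) and ACAT2 by 1.81 (SE 0.11). Fatty acid synthesis and desaturation genes rose in 7 of 11 and fell in 1 (7 and 1 adjusted over the list alone). SCD went from 167 ± 5.72 to 348 ± 16.7 FPKM (1.04, SE 0.07). Genes of G1/S and DNA replication rose in 23 of 25 (24 adjusted over the list alone) and of G2/M and mitosis in 18 of 22 (20 adjusted over the list alone), none falling. Examples are MCM4 (1.12, SE 0.15) and CENPF (1.74, SE 0.13). With an estimated correlation the calls of these 2 lists were lost (adjusted p = 0.144 and adjusted p = 0.091). For some members the third cystine-free library lay nearer the cystine libraries. BIRC5 had 3.63, 4.66 and 7.61 FPKM in the cystine-free libraries and at least 10.38 with cystine. FEN1 had 25.89, 30.11 and 41.0 FPKM and at least 64.02 with cystine. Heat shock genes rose in 9 of 13 and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.0877 with an estimated correlation), among them HSP90AA1 (0.94, SE 0.09). Nuclear-encoded oxidative phosphorylation genes rose in 14 of 26 and fell in 0 (16 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation). Interferon-stimulated genes rose in 2 of 13, OAS3 and IFIT1, and fell in 0 (2 adjusted over the list alone; adjusted p = 0.191 with an estimated correlation).

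Camera called 18 of the 30 tested lists in HCT116, 7 upward and 11 downward, and 7 with an estimated correlation: the integrated stress response, transporters, NRF2 targets, endoplasmic reticulum chaperones, immediate early genes, cholesterol and fatty acid synthesis. Among single genes with the largest changes, UPP1, a uridine phosphorylase, fell from 36.1 to 2.26 FPKM (−4.02, SE 0.17). LURAP1L fell from 10.3 ± 1.83 to 0.512 ± 0.0723 FPKM, and the iron-binding protein gene LCN2 from 8.69 ± 2.76 to 0.739 ± 0.191 FPKM. The Wnt antagonist DKK1 rose from 18.9 ± 8.37 to 83.4 ± 8.01 FPKM (2.12, SE 0.25). HNRNPH2 (57.2 ± 2.46 against 5.26 ± 0.372 FPKM) and the overlapping read-through model RPL36A-HNRNPH2 (1.67 ± 0.759 against 36.2 ± 1.12 FPKM) share sequence and are uncertain.

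**Figure D1:**
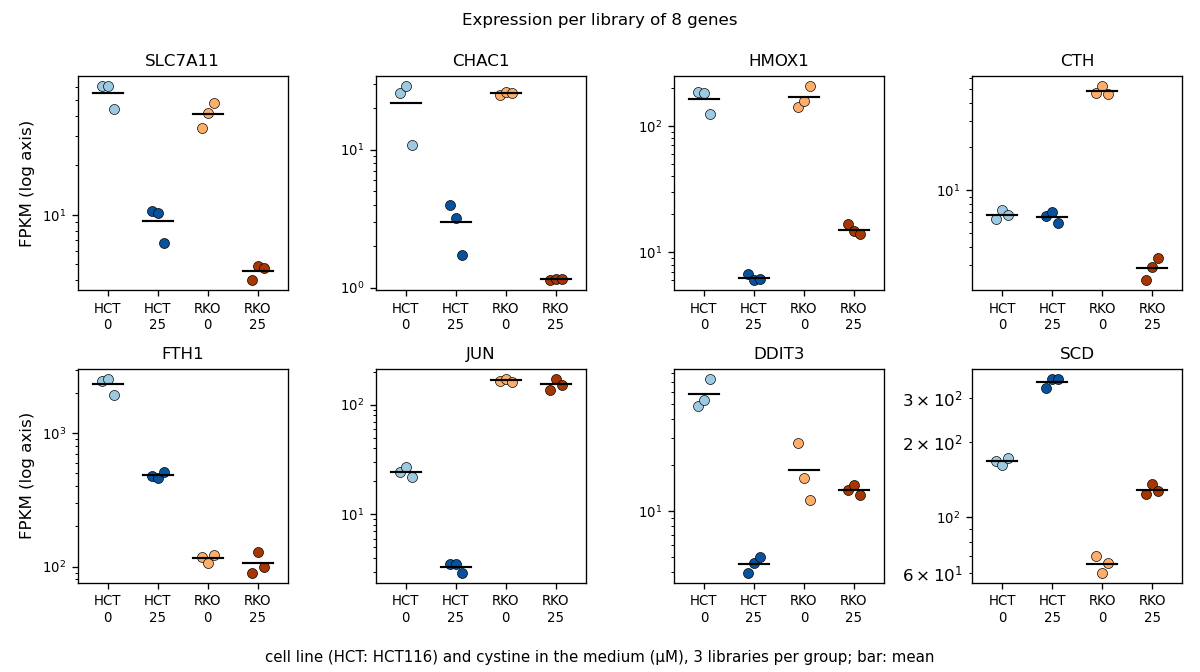
FPKM per library (log axis) of 8 genes in the 4 groups; points are single libraries and bars the mean of 3. SLC7A11, CHAC1 and HMOX1 were lower with cystine in every library of both lines, whereas CTH was lower with cystine in RKO (49.1 against 2.89 FPKM) and FTH1, JUN and DDIT3 in HCT116, and SCD was higher with cystine in both.

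The second question was the response of RKO to the same media. The same genes of cystine import, glutathione and haem breakdown were lower with cystine there too. SLC7A11 fell from 41.0 ± 7.25 to 4.55 ± 0.485 FPKM (−3.21, SE 0.22, adjusted p = 5.63e-06), CHAC1 from 25.6 ± 0.532 to 1.15 ± 0.0158 FPKM (−4.51, SE 0.40) and HMOX1 from 167 ± 35.2 to 15.1 ± 1.36 FPKM (−3.51, SE 0.19). CTH (chromosome 1, 70411218 to 70439851), the last enzyme of transsulfuration, fell from 49.1 ± 3.48 to 2.89 ± 0.503 FPKM (−4.12, SE 0.15, adjusted p = 4.56e-07). Cholesterol synthesis genes were higher with cystine, and MCM3 of DNA replication rose from 18.2 ± 1.97 to 51.1 ± 5.98 FPKM (1.44, SE 0.12).

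In RKO 4660 genes passed the edgeR test, 2358 higher and 2302 lower with cystine, 476 and 567 of them by at least 2-fold. The integrated stress response list fell in 14 of 18 members and rose in 0 (14 adjusted over the list alone; median −2.09), among them DDIT4 (−4.04, SE 0.22) and ASNS (−3.02, SE 0.16). SESN2 and TRIB3 fell by 2.58 and 1.75 (log2). DDIT3 had 18.7 ± 8.15 FPKM without and 13.7 ± 1.01 with cystine (adjusted p = 0.171). ATF4 went from 213 ± 9.09 to 175 ± 13.7 FPKM (−0.32, SE 0.09, adjusted p = 0.0215). This call was lost without 1 of 3 libraries (the third cystine-free or the first or second cystine replicate; highest adjusted p = 0.0757). Transporters fell in 9 of 15 and rose in 0 (9 adjusted over the list alone), with SLC3A2 at −1.83 (SE 0.10) and SLC7A5 at −1.80 (SE 0.10). Aminoacyl-tRNA synthetases fell in 13 of 20 and rose in 1 (13 and 2 adjusted over the list alone), with WARS at −2.06 (SE 0.13). Serine and one-carbon metabolism fell in 7 of 11 and rose in 2 (7 and 4 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation). PSAT1 was at −2.07 (SE 0.14), MTHFD2 at −1.63 (SE 0.13), SHMT2 at −0.74 (SE 0.06) and PHGDH at −0.77 (SE 0.10). Cytosolic ribosomal protein genes fell in 22 of 74 and rose in 2 (22 and 2 adjusted over the list alone; adjusted p = 0.516 with an estimated correlation). RPL5 fell by 0.69 and RPS3 by 0.51 (log2). Many of them have processed pseudogenes and are uncertain where reads could be split.

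The p53 targets fell in 8 of 19 and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.276 with an estimated correlation), GADD45A by 2.43 (log2). Autophagy and lysosome genes fell in 9 of 22 and rose in 0 (9 adjusted over the list alone; adjusted p = 0.104 with an estimated correlation). Among them were WIPI1 (−1.68, SE 0.17) and GABARAPL2 (−1.39, SE 0.12). Immediate early genes fell in 6 of 18 and rose in 2 (6 and 3 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation). FOSL2 fell by 1.27 and IER3 by 1.40 (log2), while JUN had 166 ± 6.65 and 153 ± 17.7 FPKM (adjusted p = 0.274). The NRF2 list was not called in RKO (adjusted p = 0.121), with 5 members lower and 4 higher (5 and 4 adjusted over the list alone). GCLM fell by 0.79 and TXNRD1 by 1.64 (log2), the latter over cystine-free libraries that spread widely (200 ± 123 FPKM), while TKT of the pentose phosphate pathway rose by 1.10. GCLC, FTH1 and FTL gave adjusted p = 0.292, 0.337 and 0.855. GPX4 rose by 0.50 (log2, SE 0.13, adjusted p = 0.0119), TFRC had 33.8 ± 10.4 and 49.5 ± 2.51 FPKM (adjusted p = 0.0538), and CDKN1A had 10.6 ± 3.43 and 22.5 ± 11.2 FPKM (adjusted p = 0.184).

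Higher with cystine in RKO were 18 of 20 cholesterol synthesis genes, none falling (19 adjusted over the list alone; median 0.72), among them DHCR7 (1.25, SE 0.12) and ACAT2 (1.14, SE 0.11). So were 7 of 11 fatty acid synthesis genes with none lower (7 and 1 adjusted over the list alone), SCD by 0.94. G1/S genes rose in 21 of 25 (22 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation), none falling. G2/M genes rose in 12 of 22 (12 adjusted over the list alone; adjusted p = 0.443 with an estimated correlation), none falling. Heat shock genes rose in 9 of 13, none falling (11 adjusted over the list alone; adjusted p = 0.104 with an estimated correlation), HSPE1 by 1.43. Nuclear-encoded oxidative phosphorylation genes rose in 15 of 26, none falling (16 adjusted over the list alone; adjusted p = 0.345 with an estimated correlation). Interferon-stimulated genes rose in 6 of 13 and fell in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.345 with an estimated correlation). OAS3 was at 1.25 (SE 0.12) and ISG15 at 0.97 (SE 0.13). Mitochondrially encoded genes rose in 4 of 15 (4 adjusted over the list alone; adjusted p = 0.608 with an estimated correlation). MT-ATP6 went from 2384 ± 135 to 14850 ± 4174 FPKM (2.61, SE 0.22), while counts summed over overlapping or near-identical models rose 1.76-fold, in libraries whose mitochondrial share was the variable one given at the start. Of 7 replication-dependent histone genes 3 rose (3 adjusted over the list alone; adjusted p = 0.157 with an estimated correlation). HIST1H1C rose from 7.42 ± 0.946 to 62.3 ± 7.12 FPKM.

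Camera called 17 lists in RKO, 9 upward and 8 downward, and 5 with an estimated correlation: the integrated stress response, transporters, aminoacyl-tRNA synthetases, cholesterol and fatty acid synthesis. The largest single changes included LY96, the TLR4 co-receptor MD-2, from 62.8 to 0.437 FPKM. The lipoxygenase family gene ALOXE3 fell from 8.28 ± 0.355 to 0.240 ± 0.0767 FPKM (−5.14, SE 0.29), and SUN3 (−3.72, SE 0.15) and TSC22D3 (−3.73, SE 0.29) fell too. MAP1LC3C rose from 54.2 ± 15.3 to 296 ± 21.8 FPKM (2.41, SE 0.38), PALM3 by 2.56 and the intermediate filament gene NES by 2.07 (log2).

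Both lines shared part of the response. By the threshold, 1734 genes were called in HCT116 only and 2457 in RKO only, which is not itself a test of a difference. Of 2203 genes called in both, 2030 had the same direction, 1063 higher and 967 lower with cystine, where independent lists of these sizes would share 345.6 and 333.8. Opposite calls numbered 87 (higher in HCT116) and 86 (higher in RKO), against 337.4 and 341.9 for independent lists. Stress genes SESN2, PPP1R15A and GADD45A, the transporters SLC7A11, SLC3A2 and SLC7A5, and SARS and WARS fell in both, and SCD, MCM4 and HSP90AA1 rose in both. Across all 13504 genes, which are not independent replicates, the fold changes correlated at Pearson r = 0.241 and Spearman rho = 0.404. The tests share no libraries, but share the estimate of the spread.

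**Figure D2:**
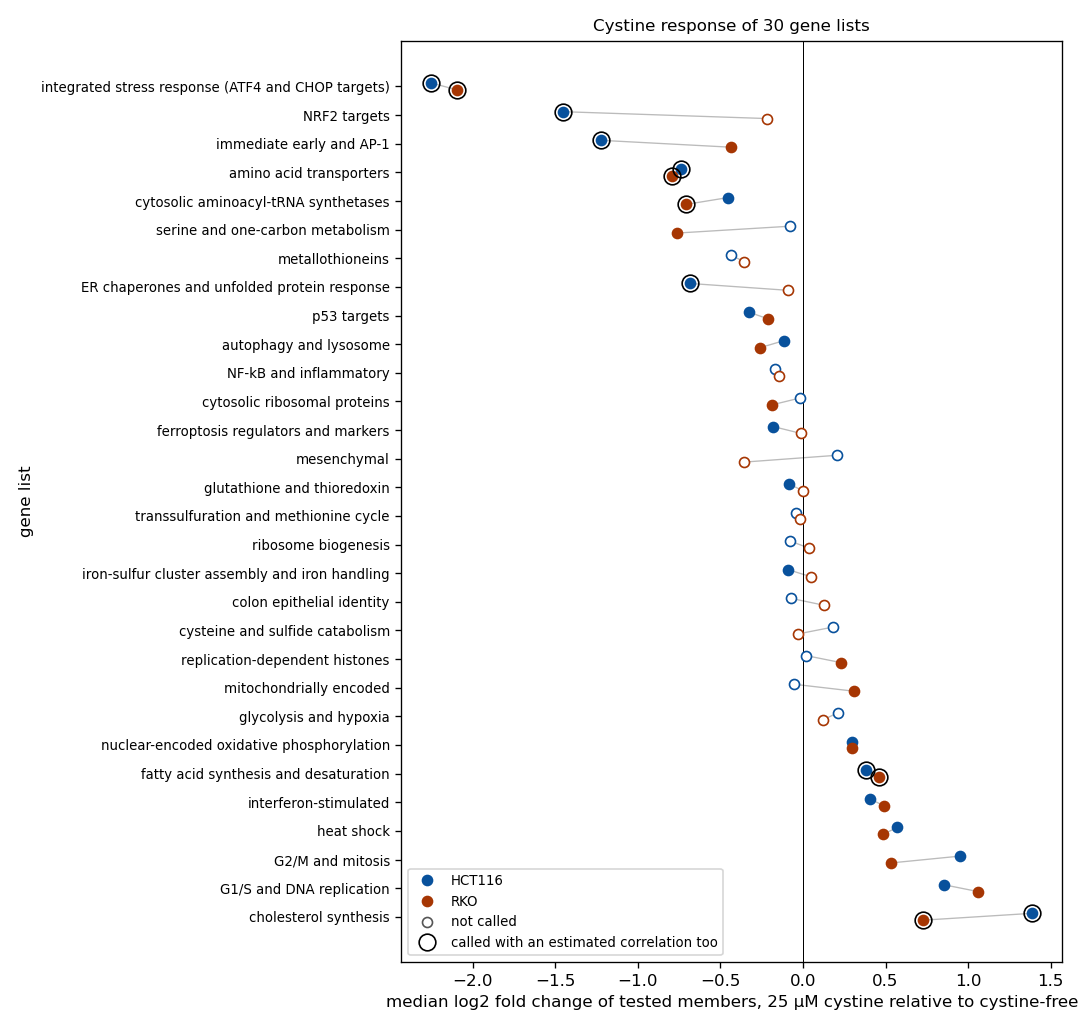
Median log2 fold change (25 µM cystine relative to cystine-free) of the tested members of 30 gene lists in HCT116 and RKO, n = 3 libraries per group; filled points are lists called by camera with the preset correlation and ringed points those called with an estimated correlation too. The integrated stress response lies lowest in both lines (−2.25 and −2.09), and NRF2 targets at −1.45 in HCT116 and −0.22 in RKO.

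Whether the response differed between the lines was tested as an interaction (RKO log2 fold change minus that of HCT116). CTH fell in RKO and not detectably in HCT116 (interaction −4.05, SE 0.20, adjusted p = 9.58e-06). JUN fell in HCT116 and did not change detectably in RKO (interaction 2.74, SE 0.16, adjusted p = 1.25e-05), and DDIT3 showed the same contrast (3.21, SE 0.38, adjusted p = 0.000792). Of the NRF2 targets 12 of 20 had a positive interaction, meaning a smaller fall or a rise in RKO, and 1 a negative one (12 and 1 adjusted over the list alone; median 0.98; adjusted p = 0.0704 with an estimated correlation). FTH1 (2.11), FTL (1.76), SRXN1 (1.76), NQO1 (1.55), GCLC (1.38) and HMOX1 (1.19) were among them. SLC7A11 (−0.62, adjusted p = 0.185) and TXNRD1 (0.30, adjusted p = 0.754) were not.

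Altogether 1744 genes passed the edgeR interaction test, 858 with a higher and 886 with a lower value in RKO. Of these, 544 were called in HCT116 alone, 757 in RKO alone, 173 in opposite directions, 100 in the same direction with the larger change in HCT116, 133 with the larger change in RKO, and 37 in neither line. Endoplasmic reticulum chaperones had a positive interaction in 10 of 18 and a negative one in 0 (13 adjusted over the list alone; adjusted p = 0.0704 with an estimated correlation). HYOU1 was at 1.46 and HSPA5 at 1.22. Immediate early genes had 7 positive and 1 negative of 18 (7 and 1 adjusted over the list alone; adjusted p = 0.0558 with an estimated correlation). KLF10 was at 2.41 and EGR1 at 1.73. Cholesterol synthesis genes rose more in HCT116 in 7 of 20 (8 adjusted over the list alone; adjusted p = 0.0704 with an estimated correlation), INSIG1 by 1.57. The integrated stress response list was not called, with 4 positive and 3 negative of 18 and 11 not passing (5 and 4 adjusted over the list alone; median −0.02). DDIT3, GDF15 and CEBPG had positive and CTH, DDIT4 and ASNS negative interactions. The other 6 called lists were G2/M (median −0.43), ribosomal proteins (−0.17), iron-sulfur and iron handling (0.36, with FTH1 and FTL), transsulfuration (−0.07, where CTH was the single member to pass), histones (0.61, HIST1H1C and HIST1H2BD) and glutathione and thioredoxin (0.15). Their adjusted p with an estimated correlation was 0.598, 0.598, 0.0558, 0.0992, 0.194 and 0.497 in that order.

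Large interactions without a floor in either line were those of VGF, a secreted neuropeptide precursor (16.3 ± 1.11 to 1.79 ± 0.430 FPKM in HCT116, 2.64 ± 0.535 to 4.24 ± 0.683 in RKO; adjusted p = 8.84e-05), ALOXE3 (adjusted p = 8.84e-05) and the read-through model TVP23C-CDRT4, which is uncertain. Other genes picked by size were near 0 in 1 line, so that their fitted interaction is no measure of size. They were FGF19, KLK7, MLPH and PSTPIP2 (61.7, 29.5, 6.62 and 7.00 FPKM in cystine-free HCT116, group means of at most 0.0452 in RKO). CRIP1, CSTA and MFAP2 (6.30, 15.3 and 6.35 FPKM in cystine-free HCT116, group means of at most 0.163 in RKO), and LY96 and DGKI (62.8 and 9.05 FPKM in cystine-free RKO) were others. The interaction count depended on single libraries. It was 1157 without the second cystine replicate of HCT116 and 1124 without the second cystine-free replicate of RKO. It was 1030 without a filter on low values, 2259 with limma on log2(FPKM + 1) and 2991 with library weights in the same limma test.

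**Figure D3:**
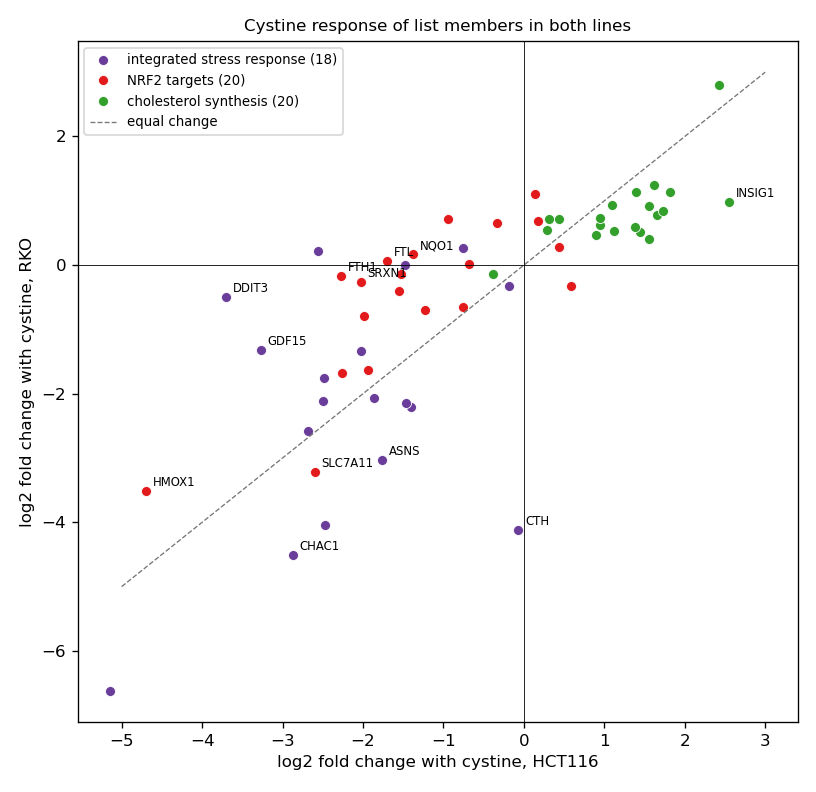
Log2 fold change with cystine in HCT116 (x axis) and RKO (y axis) for the tested members of 3 lists, with the line of equal change. Integrated stress response and cholesterol synthesis genes lie in the same quadrant in both lines, except for a few, and most NRF2 targets lie above the line, lower with cystine in HCT116 than in RKO.

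The lines themselves differed at most genes, with both media weighted equally. Colon epithelial genes were lower in RKO. Of 8 tested members 7 were lower and 0 higher (7 adjusted over the list alone; median −7.15). Among them were the adhesion molecules EPCAM (137 ± 10.2 FPKM in cystine-free HCT116, 5.19 ± 0.846 in RKO; −4.78, SE 0.11) and CDH1 (23.9 ± 6.72 and 0.0375 ± 0.0204 FPKM). So were the keratins KRT8, KRT18 and KRT19 (−5.41, −2.54 and −9.60). CDH1, KRT19, KRT20 and ELF3 were at or near 0 in RKO (at most 0.37 FPKM in any library). Their fitted values, and the list median that depends on them, are therefore no measure of size. CDX2 had 2.28 ± 0.106 and 2.47 ± 0.231 FPKM (adjusted p = 0.417). Mesenchymal genes went both ways, 4 higher and 4 lower of 8 (4 and 4 adjusted over the list alone). Higher in RKO were ZEB1 (6.74, SE 0.39), AXL (3.38, SE 0.09), VIM (2.36, SE 0.16) and TGFB1I1 (1.39, SE 0.10), and lower were SPARC (−4.87, SE 0.50), FN1 (−3.04, SE 0.18), CALD1 (−1.17, SE 0.16) and SNAI1 (−0.66, SE 0.16). SPARC had at most 12 counts in any cystine library of RKO, so its fitted value is no measure of size.

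In all 9575 of 13504 genes passed the edgeR test, 4692 higher and 4883 lower in RKO, 1572 and 2316 of them by at least 2-fold. Metallothioneins, which bind zinc and copper, were higher in RKO in 5 of 5 tested members (5 adjusted over the list alone), MT2A at 854 FPKM in cystine-free RKO and 306 in HCT116. Fatty acid synthesis genes were lower in RKO in 8 of 11 and higher in 3 (8 and 3 adjusted over the list alone; adjusted p = 0.093 with an estimated correlation). NRF2 targets were lower in 15 of 20 and higher in 4 (15 and 4 adjusted over the list alone; adjusted p = 0.589 with an estimated correlation). Ribosomal protein genes were higher in 54 of 74 and lower in 2 (54 and 2 adjusted over the list alone; adjusted p = 0.923 with an estimated correlation). The largest fitted differences were of genes at or near 0 in 1 line, where the fitted value is no measure of size. MAOB, MAGEA2, CSAG3, ARMC4, PDE9A and TMEM200A had 0 counts in all 6 RKO libraries, which puts them at least 218-, 188-, 111-, 147-, 145- and 223-fold higher in HCT116 against a floor of 12 counts (3 fragments) per library. PDCD1LG2 and TRBV12-3 had 0 counts in HCT116 and were at least 89.0- and 29.3-fold higher in RKO. CCDC190 and ZNF486 stayed at or under the floor in HCT116 (at least 143- and 108-fold higher in RKO), and HGF had 13.3 ± 1.32 FPKM in cystine-free RKO. MAGEA2, CSAG3 and TRBV12-3 belong to families of near-identical copies, and TGIF2-RAB5IF is a read-through model, so these 4 are uncertain. CALD1 differed between the lines with cystine but not without it (log2 difference 0.05, adjusted p = 0.877 in cystine-free medium). SNAI1 was not called in cystine-free medium (adjusted p = 0.197), but its interaction did not pass (adjusted p = 0.256).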

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

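The interaction test and the splits were planned, while the tests on NRF2 targets, MT-ATP6 and HNRNPH2 were chosen after these results were seen, with predictions written before the test for NRF2 targets only. The cystine effect differed between HCT116 and RKO, by the interaction test, at 1744 genes. It differed in 10 gene lists, by median log2 difference (RKO minus HCT116): NRF2 targets 0.98, immediate early genes 0.68, histones 0.61, endoplasmic reticulum chaperones 0.57, iron-sulfur assembly and iron handling 0.36, glutathione and thioredoxin 0.15, transsulfuration −0.065 (mean −0.52), ribosomal proteins −0.17, cholesterol synthesis −0.39 and G2/M −0.43. None of the 10 was called with an estimated correlation.

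Genes named in the text that passed the same test are given with their log2 difference. Of the NRF2 targets and iron stores these were FTH1 2.11, FTL 1.76, SRXN1 1.76, NQO1 1.55, GCLC 1.38, GCLM 1.198, HMOX1 1.19 and TKT 0.97. Of stress, amino acid and autophagy genes these were DDIT3 3.21, GDF15 1.96, CEBPG 0.69, CTH −4.05, DDIT4 −1.56, ASNS −1.27, SHMT2 −0.66, GOT1 −0.58, TNFRSF10B 0.81, SQSTM1 1.27, WIPI1 −1.01, GABARAPL2 −1.43, HSPA5 1.22 and HYOU1 1.46. Of immediate early genes these were JUN 2.74, KLF10 2.41, EGR1 1.73 and FOSL1 1.40. Of genes of sterol synthesis, cell cycle and ribosomes these were INSIG1 −1.57, SQLE −0.93, ACAT2 −0.68, CENPF −1.23, MCM3 0.67, RPL5 −0.66 and RPS3 −0.88. Among the others they were ALOXE3 −4.92, AXL 0.73, CALD1 −2.42, FN1 −1.16, HIST1H1C 2.57, HIST1H2BD 1.33, ISG15 0.70, KRT18 0.86, MT-ATP6 2.80, MT1X 0.79, MT2A 1.17, NES 0.89, NFKB2 −0.57, SUN3 −1.65, TSC22D3 −1.41, TVP23C-CDRT4 3.59, UPP1 2.52, VGF 3.82 and VIM 1.22. For genes near 0 in 1 line the fitted differences, FGF19 8.14, KLK7 7.01, MLPH 5.88, PSTPIP2 5.50, CRIP1 −5.61, CSTA −5.22, MFAP2 −4.99, LY96 −4.70, DGKI −4.28, SPARC −3.31 and DKK1 −1.78, are no measure of size.

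Other splits of the libraries were tested for each count. The true media split of HCT116 gave 3937 calls and the highest of the other splits 5, and in RKO 4660 and 8; the true split was the 1 of 10 with the largest count in each line, and 10 splits are too few for a share under 0.05. By the same splits, 18 lists were called in HCT116 and at most 15 otherwise (1 of 10), and 17 and at most 11 in RKO (1 of 10). Lists called with the preset correlation are therefore weak evidence on their own: the other splits gave at least 7 and 3. With an estimated correlation the true splits gave 7 and 5 lists and the others 0. Every other split mixed both media within a group, so the cystine effect entered the spread and the estimated correlation. The low counts of the other splits, of genes and of these lists, were therefore partly built in and are weak support. The line difference (9575 against at most 1660) and the genes called in both lines in 1 direction (2030 against at most 2) were the largest of 100 splits, 1 of 100 each. The other splits here mixed lines or media within groups as well. For the interaction 2 of 100 splits gave as many calls, the true one with 1744 and one with 2236. In that other split RKO kept its labels and the HCT116 media were partly exchanged, so the cystine effect of RKO itself entered the difference, and these splits are no clean reference for the interaction. A first draw of 40 splits also held these 2, a share of 0.05; it was replaced by 100 after this was seen, because 100 had been prescribed, and the lower share comes from the larger draw.

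The weaker NRF2 response of RKO was weighed against 3 technical or general explanations. Among genes called in both lines in 1 direction, 45.2% had the larger fold in HCT116, so a smaller response of every gene in RKO does not explain it. The median difference was 0.93 or more with median-ratio and quantile scaling and 0.76 or more without any single library, which speaks against scaling and a single library as causes. A difference between the lines in NRF2 regulation may remain, but the list has adjusted p = 0.0704 with an estimated correlation, and no biological explanation was tested.

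MT-ATP6 rose in RKO alone. Summed over MT-ATP6, MT-ATP8, MT-CO3 and the nuclear copy MTATP6P1, counts were 1.76-fold higher with cystine in RKO (adjusted p = 0.00905; interaction 1.02, adjusted p = 0.0364, against 2.80 for MT-ATP6), and none of the other 3 models was called lower, so coverage moved between these models does not explain the whole rise. The other mitochondrially encoded genes had a median log2 change of 0.27 in RKO. No biological explanation was tested.

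HNRNPH2 was lower with cystine in HCT116. In 12 of 12 libraries 1 of HNRNPH2 and its read-through model stood at least 2-fold above the other, and the read-through model was on top in 0 of 3 cystine-free and 3 of 3 cystine libraries of HCT116, and in 1 of 3 and 2 of 3 of RKO. Reads given to 1 model or the other could explain the fall of 3.46 (log2). The summed counts of both models also fell in HCT116, by 1.85 (log2, adjusted p = 0.0349), but the sum is no bound, since within cystine-free RKO it was 3030 counts in the library with the read-through model on top and 12532 and 12832 in the other two. No biological explanation was tested.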

How the results depend on the processing

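All alternatives here were planned except DESeq2 and counts divided by 4, which were chosen after the data were seen. The limma test on log2(FPKM + 1) had been planned as the main test for FPKM values. It became an alternative once edgeR on the estimated counts was chosen. It called 4316 genes in HCT116, 4657 in RKO and 9650 for the line difference. No alternative turned the direction of a called list. The order of higher and lower calls turned under some alternatives, in RKO from 2358 higher and 2302 lower to 2204 and 2451 with median-ratio scaling. For the line difference no filter on low values gave 5470 higher and 8535 lower calls, against 4692 and 4883. Of 505 gene results 381 kept their call throughout, 57 lost it and 63 gained it under at least 1 alternative, and 7 reversed. Asking for at least 2-fold left 827 calls in HCT116, 1043 in RKO, 600 for the interaction and 3888 for the line difference, and an adjusted p under 0.01 left 2231, 2833 and 566 in the first 3, by construction. A filter at 5 FPKM tested fewer genes and left 5378 for the line difference. The interaction had 1030 calls with no filter, 2259 with limma on log2(FPKM + 1) and 2991 with library weights in the same limma test; the cause was not tested. An estimated correlation left 7 lists in HCT116, 5 in RKO, 0 for the interaction and 2 for the line difference. Fry called 22, 23, 11 and 26 in that order, against 18, 17, 10 and 5 with the preset correlation. The 2 alternatives thus moved the list counts in opposite directions. Without each library in turn, with the remaining pair assumed to vary like the other groups, counts ran from 2923 to 4155 in HCT116, 3619 to 4678 in RKO, 1124 to 1535 for the interaction, 9197 to 9414 for the line difference and 1587 to 2000 for genes shared by both lines, and lists from 16 to 20 and 15 to 18.

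Reversed results were interactions of genes near 0 in at least 1 group, apart from the line difference of CALD1. With a pseudocount of 0.1 they were 0.53 for CSTA and −2.09 for KRT20. With limma on log2(FPKM + 1) they were 1.47 (CSTA), 0.53 (HGF), −1.47 (KRT20) and 2.11 (MAP1LC3C). With quantile scaling in the same limma test they were 1.35 (CSTA), 0.45 (HGF), −1.56 (KRT20), 1.01 (LURAP1L) and 2.12 (MAP1LC3C), and with library weights 1.48, 0.54, −1.43, 0.67 and 2.20 in that order. A pseudocount shrinks fold changes of values near 0 by construction. LY96, with at most 11 counts in any cystine library of HCT116, ranged from −5.30 to 0.16 without each library in turn, and the cause was not tested. CALD1 differed between the lines by 0.045 in cystine-free medium alone. Its interaction was −2.42, so its line difference depended on the medium. The replicate number as a block within each line gave 3772 and 4541 calls in HCT116 and RKO. Deviations from the group means were correlated between libraries of 1 number in the same line. These correlations were 0.05, −0.03 and 0.04 in HCT116 and 0.027, 0.036 and −0.032 in RKO. They show no pairing by number, but so few pairs cannot exclude it. At the depth of these libraries the interaction recovered 26.4% of simulated 2-fold changes.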

Other observations

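Genes and tests in this part were chosen after the results were seen. Several genes outside the called lists moved in the same direction in both lines. Of the glycolytic enzymes, LDHA, which makes lactate, rose by 0.68 (log2, SE 0.17) in HCT116 and by 1.12 (SE 0.17) in RKO, and PGK1 (0.72 and 0.66), ENO1 (0.35 and 0.44) and PFKFB4 (0.86 and 0.99) rose in both. The angiogenic factor VEGFA fell, from 10.7 ± 0.972 to 3.15 ± 0.330 FPKM in HCT116 and from 7.82 ± 0.502 to 1.76 ± 0.501 in RKO (mean ± SD, n = 3 libraries). The glycolysis and hypoxia list holds both and was not called (8 higher and 4 lower of 21 in HCT116, 8 and 6 in RKO; adjusted p = 0.261 and 0.465). GOT1, a transaminase that also acts on cysteine, fell by 1.24 and 1.82 (log2), and RRP12 of ribosome biogenesis fell by 0.82 and 1.16. The cysteine and sulfide catabolism list (adjusted p = 0.467 and 0.252) and the ribosome biogenesis list (adjusted p = 0.467 and 0.881) were not called in HCT116 or RKO.

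Metallothioneins MT1X and MT2A fell in HCT116 by 1.19 and 1.16 (log2), and in RKO MT1X fell by 0.40 while MT2A had an adjusted p of 0.985; MT1E fell by 0.44 and 0.36. Near-identical copies make all 3 uncertain, and the list was not called (adjusted p = 0.113 and 0.655), its median of −0.44 in HCT116 differing in sign from its mean of 1.03. Of 5 tested members 3 fell and 1 rose in HCT116, where the highest log2 change was 4.46. In RKO 2 fell and 0 rose, with a highest log2 change of 1.02. In the inflammatory list CXCL8 and RELB fell in HCT116 by 2.81 and 0.91, and NFKB2 fell in RKO by 0.67 (list adjusted p = 0.115 and 0.552). Epithelial and mesenchymal lists were not called for cystine (adjusted p = 0.839 and 0.889 in HCT116, 0.734 and 0.369 in RKO). The fibroblast list had 1 tested member, the leukocyte and erythroid list 1, CD68, at 128 FPKM in cystine-free RKO and 0.735 in HCT116, and the endothelial list 0, so none of the 3 was tested.

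Camera over KEGG pathways called 37 in HCT116, 29 in RKO and 2 for the interaction, and with an estimated correlation 1 (steroid biosynthesis), 0 and 0. GO terms gave 121, 125 and 3, and 0 in each with an estimated correlation.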
